A study of Mus musculus with 50 samples.

How the data were processed

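Messenger RNA was measured by paired-end sequencing of poly(A)-selected RNA in the colon epithelium of 50 male C57BL/6J mice, 1 library per labelled sample, in 10 groups of 5. The labels give no litter or cage and do not say that samples came from separate mice. P-values thus measure the spread between these samples. The authors made 1 table of read counts per gene, with 78275 genes named by mouse Ensembl identifiers and symbols. Per the submitters' processing notes the reads were trimmed with Trim Galore, aligned with HISAT2 and counted with featureCounts, and versions, settings, strand and the annotation release are not given in the sources used here. The same notes name the human build GRCh38, whereas the identifiers in the deposited table are mouse genes, so no coordinates are reported and gene names are those of the table.

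The deposited values were whole-number counts per gene that differed in total between libraries, from 30,658,656 to 43,296,403, with a median of 37,110,909. The labels state 150-base paired reads, and the totals lie between the stated number of pairs and the stated number of reads. Of the values from 1 to 4, 70.9% were even, against 53.5% of the values from 100 to 999, as if both mates of a pair were often counted apart. Counting error is then larger than the counts alone would give, which an alternative with every count divided by 2 addresses. PCR duplicates carry no molecular identifiers, so all errors given here come from the spread between libraries. No pair of libraries within a group was a duplicate, since the 100 pairs differed by 14.1 to 480.2 times the chi-square per degree of freedom that counting alone gives. Levels of X- and Y-linked genes matched the male label in 50 of 50 libraries. All 50 columns matched a labelled library by name. For isovalerate the route of the titles and protocol, the enema, was used. No batch is recorded. The library numbers of the enema experiment form 2 runs, and the first holds no library of isovalerate on the control diet, so the runs are unbalanced across the groups.

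Counts as deposited were tested with edgeR 4.0.16 (R 4.3.3). Genes were kept with filterByExpr by group, with its minimum count of 10 and minimum total of 15, which left 19866 genes in the 30 gavage libraries and 18614 in the 20 enema libraries. Libraries were scaled with TMM, 1 mean was fitted per group with the robust quasi-likelihood model, and each contrast was tested with the quasi-likelihood F test. P-values were adjusted by Benjamini-Hochberg over all tested genes of a contrast with a threshold of 0.05 and no fold limit. The gavage and the enema experiment were fitted apart, because route, vehicle and cohort differ between them, and 1 contrast between them was fitted over all 50 libraries. A log2 fold change is given ± its standard error, derived from the F statistic, and each group mean is a mean in CPM computed from the deposited counts with TMM scaling, ± SD over 5 libraries. The number of libraries that show a direction is the number of libraries of the first group that lie on that side of the mean of the second.

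Lists of genes fixed in advance, 46 in number, were tested with camera (limma 3.58.1) at its preset correlation of 0.01, adjusted over the lists of each comparison, with at least 5 tested members required. Camera asks whether the members of a list rank higher or lower than other genes. Its calls at the preset correlation were repeated with a correlation estimated from the residuals, which widens the error of lists whose members move together between libraries, and with fry, which asks whether the members move 1 way on balance without comparing them with other genes (in its mixed form, whether they move either way). Over 17 comparisons the preset correlation called 235 of 782 list tests, the estimated correlation 8 and fry 16. A list score is the mean over members of the log2 CPM (prior count 2) centred on the experiment, and scores were compared by exact two-sided permutation of 5 against 5 libraries, whose smallest possible p is 0.00794. No score passed adjustment over the lists of its comparison. Symbols of the lists were matched to the table directly or through an older name, and 3 lists had a symbol with no match. Where "adjusted over the list alone" is written, Benjamini-Hochberg was applied to the members of that list.

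Genes named in the text were taken by a rule fixed in advance. Among genes past the threshold with a mean of at least 1 CPM in 1 of the groups compared and a symbol that is not a predicted, clone or pseudogene name, the 10 with the largest rise and the 10 with the largest fall were eligible, as were up to 4 members of each list in order of p. Where no gene passed, the 5 genes with the smallest p were eligible as values that did not pass, and members of a list may be given with values that did not pass. The contrasts, tests, lists, naming rule and most alternatives were chosen before the data were examined.

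The edgeR step was tested on simulated counts drawn from the average level and dispersion of each gene and the library sizes of each experiment, in 1 draw each. In the simulated gavage diet comparison over 19783 genes, 19.0% of 100 genes changed 1.5-fold and 44.4% of 99 genes changed 2-fold were recovered, with 3.03% of calls false. In the simulated enema diet comparison over 18454 genes, 37.0% of 100 genes changed 1.5-fold and 56.0% of 100 changed 2-fold were recovered, with 3.06% of calls false. A list shifted by 0.3 on the log2 scale was called in both and no other was. Genes were drawn independently, so lists whose members move together went untested. On these counts 13.6% (gavage) and 16.5% (enema) of DESeq2's calls were false.

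Alternatives fixed in advance were scaling by RLE, DESeq2 1.42.0, limma voom with sample weights, no filter on low counts, a filter of 5 CPM in 5 libraries, a fit of only the groups compared, the replicate number as a block, a fit of all 50 libraries, a term for the run of library numbers within the enema experiment, and leaving out each library. Alternatives chosen after seeing the data were halved counts, offsets for GC content and transcript length, a fit without 5 libraries that stand apart on a principal component or a list score, and the score of distal colon markers as a term. GC content and length were matched for 87.3% of the tested gavage genes and 89.1% of the tested enema genes. For correlations between comparisons that share vehicle libraries, 100 simulated sets of unchanged groups gave the value expected from sharing alone, and the vehicle libraries were also split into 2 and 3 so that none was shared. The protocol names both specific-pathogen-free and germ-free mice, and the labels do not say which each sample came from. Some genes that passed the threshold are not reported here by name.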

Results

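Messenger RNA of the colon epithelium was counted in 50 male mice in 10 groups of 5. Litters and their dams were placed at postnatal day 8 on a control diet, with 20% of energy from protein, 15% from fat and 65% from carbohydrate, or on a low-protein, low-fat diet (LPLFD), with 7%, 5% and 88%. The offspring were weaned to the same diet and treated at day 56. In the gavage experiment 30 mice received 114 mM leucine, 114 mM alanine or sterile water by mouth, 2 times a day for 2.5 days, which makes 6 groups over the 2 diets. In the enema experiment 20 mice received 100 mM sodium isovalerate or matched saline by rectal enema daily for 3 days, which makes 4 groups. The titles and the protocol of these samples name the enema, whereas the design text of the series names a gavage for them. The series title names a barrier dysfunction of malnutrition and isovalerate, a branched fatty acid that bacteria make from leucine. Litter and cage are not given, so neither was modelled and litter cannot be told from diet.

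In each experiment some libraries stood apart from the rest of their group. Along the first principal component of the gavage libraries, which held 23.7% of the variance, leucine control library 4 lay at 55.2 and alanine LPLFD library 5 at 75.7, and no other library lay above 15.4. Leucine LPLFD library 3 lay at 54.9 on the second component (7.63%), with a TMM factor of 0.856 and a score of 1.44 for cytosolic ribosomal proteins. In the enema experiment vehicle LPLFD library 4 lay at 73.2 on the first component (22.2%) and isovalerate control library 1 at 47.2 on the second (11.2%). Scores of the distal colon markers were -4.40 in alanine LPLFD library 5 and -4.34 in enema vehicle LPLFD library 4. Counts without these 5 are given where they or the called genes differed. None is in the water gavage or alanine control groups, so counts between those moved only through the shared fit.

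**Figure D1:**
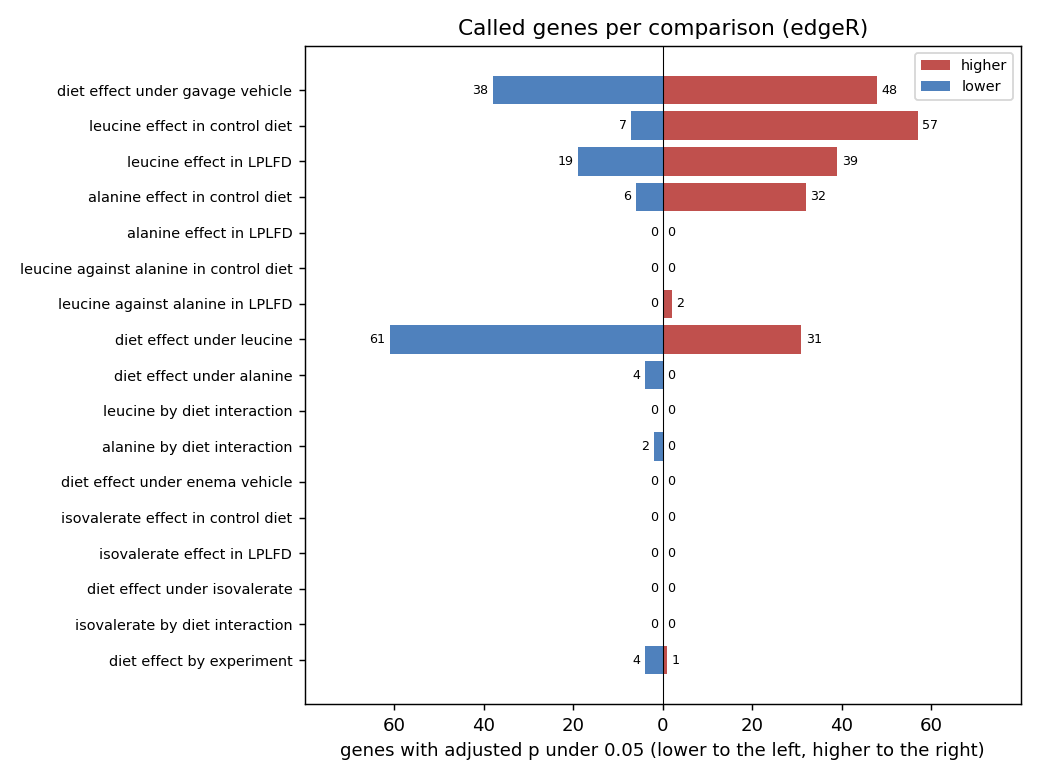
Number of genes that passed an adjusted p of 0.05 (edgeR) in each comparison, with genes higher and genes lower in the first-named group drawn apart. Each bar rests on groups of 5 libraries.

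The diet comparison under water gavage asked how the colon epithelium differed on LPLFD. Genes of cholesterol synthesis fell: of 25 measured members 24 were lower on LPLFD, 11 passed the test over all genes and 20 passed when adjusted over the list alone, with a median log2 fold change of -0.87. Idi1, an isoprenoid isomerase, fell from 48.6 ± 7.57 to 21.4 ± 5.43 CPM (SD, n = 5 per group), a log2 fold change of -1.19 ± 0.20 (SE, adjusted p = 0.00635, edgeR). Sqle (squalene epoxidase) fell from 82.4 ± 9.07 to 34.8 ± 5.39 CPM (-1.24 ± 0.25, adjusted p = 0.0151, edgeR). Each of these 2 genes was lower in 5 of 5 LPLFD libraries than the control mean. The list passed camera at the preset correlation (adjusted p = 3.96e-31) and also with an estimated correlation (adjusted p = 0.00485). Its score was -0.28 ± 0.15 on LPLFD and 0.41 ± 0.19 on the control diet (SD, n = 5 per group, exact two-sided permutation p = 0.00794, the smallest possible, and 0.0522 adjusted over the lists).

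Epithelial oxidase, mucus, lipid and transporter genes also passed under water gavage. Nox1, an NADPH oxidase of the colon epithelium, fell from 54.4 ± 9.16 to 19.8 ± 2.32 CPM (n = 5 per group, log2 fold change -1.46 ± 0.23, adjusted p = 0.00242, edgeR). Clca1, a protein secreted by goblet cells, fell from 3765 ± 677 to 2071 ± 230 CPM (-0.86 ± 0.16). Of 26 goblet cell and mucus genes 24 were lower, 1 passed over all genes and 3 passed when adjusted over the list alone. The list was called at the preset correlation, with adjusted p = 0.115 with an estimated correlation. Slc25a20, the mitochondrial carnitine carrier, rose from 167 ± 15.7 to 283 ± 24.97 CPM (0.76 ± 0.11), and Abcb1a, a drug efflux pump, rose from 544 ± 16.1 to 920 ± 71.4 CPM (0.76 ± 0.14). Of 38 fatty acid oxidation genes 27 were higher, 1 up and 1 down passed over all genes and 7 up and 1 down when adjusted over the list alone. That list had adjusted p = 0.347 with an estimated correlation, as had the xenobiotic and bile acid list (21 of 35 higher, 2 over all genes, 5 when adjusted over the list alone). Cell cycle genes were lower in 34 of 35, with Cdc6, a replication licensing factor, at -1.18 ± 0.27 and Hells at -0.95 ± 0.21. Of them 2 passed over all genes and 10 when adjusted over the list alone, and the list had adjusted p = 0.333 with an estimated correlation. Among the largest rises were the ephrin receptor Epha2 (1.92 ± 0.34), the growth factor gene Pdgfb (1.85 ± 0.40) and the transcription factors Klf11 (1.25 ± 0.22) and Klf10 (1.08 ± 0.22). Markers of T and intraepithelial lymphocytes were lower in 15 of 17 with a median of -0.93, and 0 passed over all genes and 3 when adjusted over the list alone (adjusted p = 0.158 with an estimated correlation).

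Under water gavage 48 genes rose and 38 fell on LPLFD out of 19866 (edgeR), with 1847 at an unadjusted p under 0.05. Of 16 lists called at the preset correlation, 1 held with the estimated one. The count of 86 became 46, 53, 39 and 30 without vehicle LPLFD libraries 1, 2, 3 and 5, and 30, 23 and 53 without vehicle control libraries 1, 3 and 4. With no low-count filter it was 54 and with the replicate block 66. Without the 5 libraries that stood apart it was 1041, and DESeq2 called 306 and limma voom 955.

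**Figure D2:**
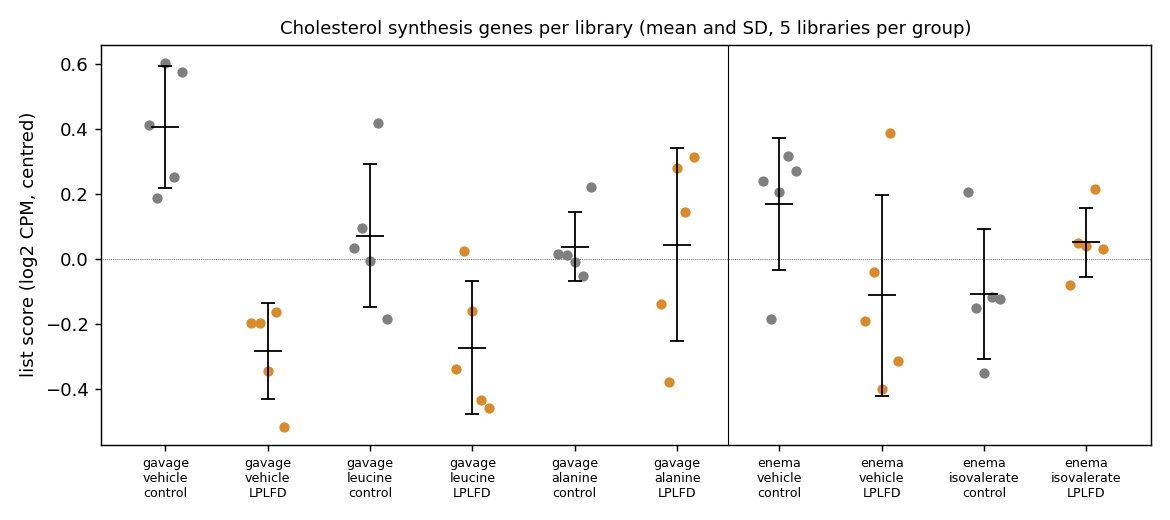
Score of the cholesterol synthesis list in each library of the 10 groups, as the mean log2 CPM of 25 genes centred within each experiment. Lines show the group mean and SD (n = 5 per group).

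The same diet comparison under saline enema gave no gene past the threshold. With edgeR 0 of 18614 genes passed, 1626 had an unadjusted p under 0.05, DESeq2 called 24 and limma voom 1. Idi1 was again among the genes with the smallest p, at 39.3 ± 9.51 CPM on LPLFD and 63.9 ± 7.67 on the control diet (n = 5 per group, log2 fold change -0.70 ± 0.14, lower in 5 of 5 libraries, adjusted p = 0.333, edgeR). Of 25 cholesterol synthesis genes 23 were lower, with a median of -0.25 and 3 genes past the threshold when adjusted over the list alone, and the list was called at the preset correlation but had adjusted p = 0.440 with an estimated correlation. Of 34 xenobiotic and bile acid genes 24 were higher and 8 passed when adjusted over the list alone, of 37 fatty acid oxidation genes 33 were higher and 3 passed so, and of 30 absorptive colonocyte genes 20 were higher and 7 passed so. These lists had adjusted p = 0.440, 0.441 and 0.693 with an estimated correlation, and enema vehicle LPLFD library 4, with the low distal score, is in this group. Goblet cell genes were not called here (17 of 26 higher, median 0.12, adjusted p = 0.369 at the preset correlation). Without vehicle LPLFD library 4 the count was 2, as it was without the 5 libraries that stood apart.

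The difference between the diet effects of both experiments was tested over 50 libraries. Epha2 had a lower diet effect under enema than under gavage (log2 difference -3.13 ± 0.55), and Btn1a1 a higher one (3.82 ± 0.76, adjusted p = 0.0428, edgeR). Of 35 cell cycle genes 35 had a higher diet effect under enema, as had 21 of 25 cholesterol synthesis genes, and 0 of either passed over all genes, against 2 and 1 when adjusted over the list alone. Both lists were called at the preset correlation and had adjusted p = 0.365 with an estimated correlation. With edgeR 1 gene had a higher and 4 a lower diet effect under enema. The count of 5 became 11 and 16 without enema vehicle LPLFD libraries 1 and 2 and 0 without 3, 4 or 5, and 1, 20, 10, 1 and 0 without enema vehicle control libraries 1 to 5. Among gavage libraries it became 1, 0, 2, 0 and 1 without vehicle LPLFD 1 to 5 and 0, 3, 0 and 0 without vehicle control 1 to 4, and 48 passed without the 5 libraries that stood apart. With the distal position score as a term, with the replicate block or with a term for the run of library numbers 0 passed, with DESeq2 43 and limma voom 36. Distal colon markers had a lower diet effect under enema in 6 of 7 (median -0.85, adjusted p = 0.0153 at the preset correlation and 0.449 with an estimated correlation), and enema vehicle LPLFD library 4 had the distal score of -4.34. Across 18425 genes the diet effects of the experiments had a Pearson r of -0.0779 and a Spearman rho of -0.0747, with a jackknife SD of r of 0.131, where genes are not independent replicates. Of the 11 cholesterol genes that fell under gavage, 11 were lower under enema, with a median of -0.37 against -1.02. Their enema score was -0.17 ± 0.38 on LPLFD and 0.21 ± 0.30 on the control diet (n = 5 per group, exact two-sided permutation p = 0.135, and p = 0.0263 from fry), a set chosen after the result was seen. The other 27 genes that fell under gavage had a median of -0.04 under enema (exact permutation p = 0.746) and the 47 genes that rose and were measured had 0.04 (exact permutation p = 0.690).

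Leucine and alanine, amino acids that differ in their side chain, were given at the same dose and schedule, so their effects on the control diet are described side by side. Leucine raised 57 genes and lowered 7, and alanine raised 32 and lowered 6 (edgeR, 19866 genes), with 2023 and 1327 genes at an unadjusted p under 0.05. Both raised Midn (log2 fold change 0.94 ± 0.15 with leucine and 0.96 ± 0.15 with alanine), the transcription factor Klf10 (1.00 ± 0.22 and 1.03 ± 0.22) and Bcl3, a partner of NF-kappaB (0.98 ± 0.18 and 0.90 ± 0.18), each in 5 of 5 libraries (n = 5 per group). Both lowered Flcn, folliculin, a regulator of mTORC1 signalling at the lysosome (-0.81 ± 0.13 and -0.64 ± 0.13). Alanine raised Irf2bpl from 28.6 ± 5.30 to 55.3 ± 5.22 CPM (SD, n = 5 per group, 0.95 ± 0.12, adjusted p = 0.000104, edgeR), and Phf13 from 13.5 ± 1.17 to 23.9 ± 1.81 CPM (0.83 ± 0.11). Leucine raised both as well (0.87 ± 0.12 and 0.87 ± 0.11), as did LPLFD under water gavage (0.61 ± 0.12 and 0.75 ± 0.11), all against the same control water libraries, and leucine against alanine was at -0.08 ± 0.12 and 0.03 ± 0.11. Alanine lowered Ankrd37, a hypoxia-induced gene, from 22.7 ± 2.46 to 7.92 ± 1.29 CPM (-1.52 ± 0.29, adjusted p = 0.0184, edgeR), with -1.14 ± 0.29 under leucine (adjusted p = 0.0889). Leucine raised the retinoic acid receptor gene Rarg (1.21 ± 0.23), the tight junction gene Cldn4 (1.05 ± 0.24), Myc (0.65 ± 0.14), the goblet cell transcription factor Foxa3 (0.88 ± 0.20), the lysosomal transcription factor Tfeb (0.58 ± 0.13) and Slc25a20 (0.51 ± 0.11).

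Of 21 lists called with leucine and 8 with alanine at the preset correlation, 0 and 1 held with the estimated one. Not all are described here. Of 31 genes of tight and adherens junctions, 27 were higher with alanine (median 0.11, 0 past the threshold over all genes or when adjusted over the list alone), and the list was called at the preset correlation (adjusted p = 0.000565) and with an estimated correlation (adjusted p = 0.0177). Without alanine control library 1 or 2 or vehicle control library 5 the estimated correlation gave adjusted p = 0.153, 0.0513 and 0.0816. With leucine 23 of 31 were higher (median 0.10, 1 over all genes and 2 when adjusted over the list alone), with adjusted p = 0.00175 at the preset correlation and adjusted p = 0.0534 with an estimated correlation. Tuft cell genes were higher in 15 of 16 with leucine, with a median of 0.86 and 5 past the threshold when adjusted over the list alone (adjusted p = 0.203 with an estimated correlation). Cholesterol synthesis genes were lower in 24 of 25 with leucine and 23 of 25 with alanine, with medians of -0.28 and -0.36, and 1 and 5 passed when adjusted over the list alone (adjusted p = 0.203 and 0.198 with an estimated correlation). Fatty acid oxidation genes were higher in 33 of 38 with leucine and 30 of 38 with alanine, 6 and 2 when adjusted over the list alone (adjusted p = 0.258 and 0.554 with an estimated correlation). Leucine control library 4 had a score of 0.89 for the fatty acid oxidation and PPAR targets against -0.16 to 0.10 in the other leucine control libraries. Among markers of other cells, those of T and intraepithelial lymphocytes were lower in 16 of 17 with alanine (median -0.63, adjusted p = 1.85e-05 at the preset correlation) and in 13 of 17 with leucine (median -0.51, adjusted p = 0.000798), 1 and 2 when adjusted over the list alone (adjusted p = 0.277 and 0.291 with an estimated correlation). With leucine smooth muscle genes were higher in 11 of 11 and erythroid genes in 4 of 5, 0 and 3 when adjusted over the list alone (adjusted p = 0.345 and 0.258 with an estimated correlation), with a score of 2.66 for other cells smooth muscle in leucine control library 1. The lists for branched-chain amino acid catabolism, mTORC1 and the ATF4 amino acid response were not called in 1 direction with leucine (adjusted p = 0.679, 0.731 and 0.0606 at the preset correlation). Members of the mTORC1 list went both ways: Tfeb was higher and Flcn lower past the threshold over all genes, Fnip1 and Fnip2 were also lower when adjusted over the list alone, and fry in its mixed form, which takes changes either way, gave adjusted p = 0.0197.

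On the control diet 27 of the genes raised by leucine and by alanine were the same, and both lists rest on the same 5 vehicle libraries, so they are not independent. Across 19866 genes the effects of leucine and alanine had a Pearson r of 0.608, where genes are not independent replicates, but both comparisons share the vehicle libraries. From differences of mean log2 CPM r was 0.628 and the covariance 0.118, and simulated unchanged groups with shared vehicle gave means of 0.485 and 0.0769 by that estimate (r from 0.121 to 0.821). Splitting the vehicle libraries gave an r of 0.214. The direct comparison of leucine with alanine on the control diet had 0 genes past the threshold (edgeR, 635 at an unadjusted p under 0.05, DESeq2 1, limma voom 0). The 95% interval of the difference between leucine and alanine lay within 2-fold for 89.7% of 13594 genes of at least 1 CPM, with a median margin of ± 0.34 on the log2 scale. Tuft cell genes were higher with leucine than with alanine in 16 of 16 (median 0.47, 0 past the threshold over all genes or when adjusted over the list alone, adjusted p = 0.477 with an estimated correlation).

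The counts on the control diet moved with single libraries. The 64 genes for leucine became 32, 42, 32 and 27 without leucine libraries 2, 3, 4 and 5 and 36, 23, 15 and 23 without vehicle libraries 1 to 4, and 259 without the 5 libraries that stood apart. The 38 genes for alanine became 16, 13, 12 and 25 without alanine libraries 2 to 5 and 22, 13, 10 and 20 without vehicle libraries 1 to 4, and 326 without those 5. With no low-count filter the counts were 40 for leucine and 25 for alanine, and with the replicate block 38 and 27. DESeq2 called 181 and limma voom 492 for leucine. For alanine DESeq2 called 78 up and 24 down, and limma voom 354 in all.

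On LPLFD, genes of the ribosome and of the respiratory chain were higher with leucine. Rps29, a ribosomal protein gene, rose from 102.2 ± 19.12 to 224 ± 118 CPM (SD, n = 5 per group, log2 fold change 1.13 ± 0.21, adjusted p = 0.0263, edgeR). Ndufb1, a subunit of complex I, rose from 16.8 ± 4.67 to 42.5 ± 24.5 CPM (1.34 ± 0.24, adjusted p = 0.0257, edgeR), each higher in 5 of 5 libraries. Of 58 cytosolic ribosomal protein genes 56 were higher (median 0.61), 1 passed over all genes and 51 when adjusted over the list alone, and of 52 oxidative phosphorylation genes 50 were higher (median 0.56), 0 over all genes and 41 when adjusted over the list alone. Both lists were called at the preset correlation and had adjusted p = 0.553 with an estimated correlation. Over the 110 members of both the median was 0.58, and 0.17 without leucine LPLFD library 3. That library had scores of 1.44 for cytosolic ribosomal proteins and 1.18 for oxidative phosphorylation, against -0.15 to 0.10 and -0.06 to 0.15 in the other libraries of its group. Duox2, an oxidase of the epithelial surface, fell from 54.7 ± 6.52 to 30.2 ± 9.97 CPM (-0.85 ± 0.18, adjusted p = 0.0385, edgeR), and Peg3 (-1.13 ± 0.18) and Clca3a2 (-0.93 ± 0.16) fell. Ftl1, the ferritin light chain, rose (0.83 ± 0.18), as did the catenin gene Ctnnd1 (0.46 ± 0.10) and the crypt transcription factor Sox9 (0.61 ± 0.14). Of 30 NRF2 antioxidant genes 27 were higher, 1 over all genes and 9 when adjusted over the list alone (adjusted p = 0.553 with an estimated correlation).

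With leucine on LPLFD 39 genes rose and 19 fell (edgeR, 3487 at an unadjusted p under 0.05), and 0 of 9 lists called at the preset correlation held with the estimated one. The count of 58 became 229, 830 and 135 without leucine libraries 2, 4 and 5, and 2, 2, 0 and 12 without vehicle LPLFD libraries 1 to 4. A fit of only the groups compared called 0 genes, the replicate block 1 and no low-count filter 2. It was 259 without the 5 libraries that stood apart, and DESeq2 called 792 and limma voom 408.

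**Figure D3:**
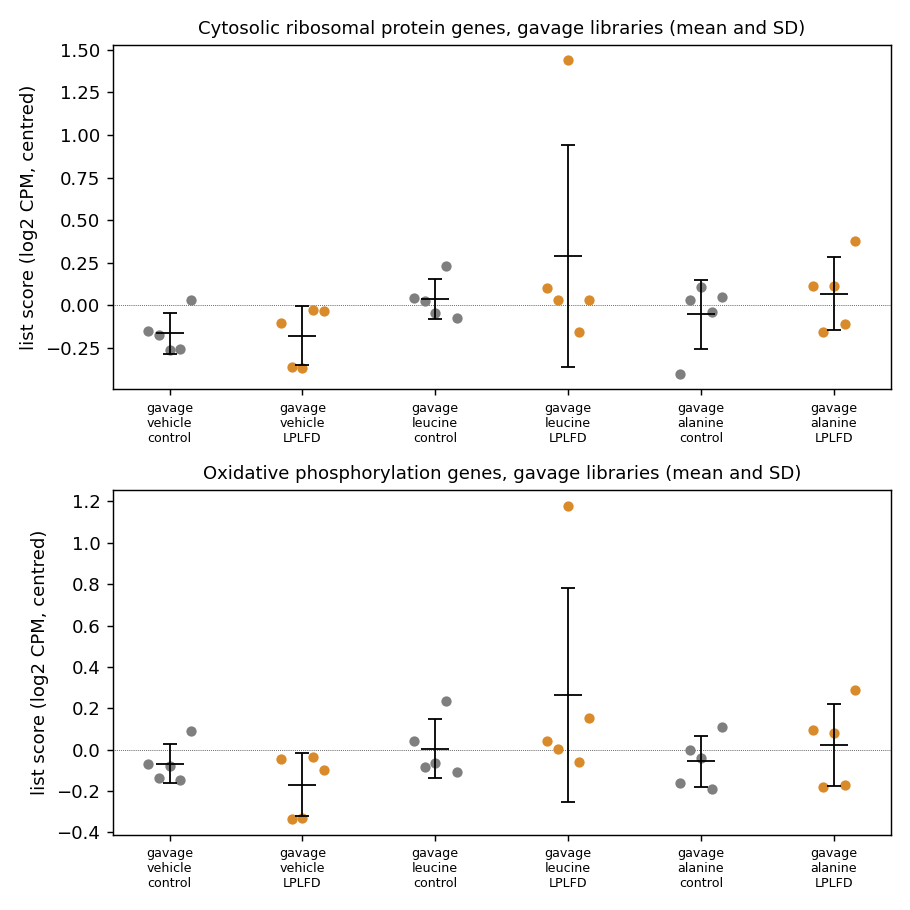
Scores of the cytosolic ribosomal protein list and the oxidative phosphorylation list in each gavage library, as mean log2 CPM centred within the experiment. Lines show the group mean and SD (n = 5 per group).

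Alanine on LPLFD gave no gene past the threshold. With edgeR 0 of 19866 genes passed, 1542 had an unadjusted p under 0.05, DESeq2 called 11 and limma voom 0. The unadjusted count was 691 without alanine LPLFD library 5. Among the genes with the smallest p were Cav2, a caveolin (0.63 ± 0.15), and Rhoc (-0.43 ± 0.10), each in that direction in 5 of 5 libraries (n = 5 per group, adjusted p = 0.381, edgeR). Cholesterol synthesis genes were higher with alanine in 23 of 25 (median 0.35) and ribosomal protein genes in 55 of 58 (median 0.26), 1 and 0 when adjusted over the list alone, with adjusted p = 0.589 and 0.624 with an estimated correlation. Goblet cell genes were higher in 22 of 26, with a median of 0.29 and 1 when adjusted over the list alone. ATF4 amino acid response genes were higher in 29 of 37, with a median of 0.16 and 0 when adjusted over the list alone (adjusted p = 0.589 and 0.624 with an estimated correlation). Distal colon markers were lower in 6 of 7, and the score of colon position distal was -4.40 in alanine LPLFD library 5 against 0.13 to 0.50 in the other libraries of that group.

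Compared directly on LPLFD at the same dose, 2 genes were higher with leucine than with alanine. They were Zfp37, a zinc finger gene (log2 difference 0.87 ± 0.16, adjusted p = 0.0457, edgeR), and Sowahb (0.62 ± 0.11), each higher in 5 of 5 libraries (n = 5 per group, 2235 genes at an unadjusted p under 0.05). Cholesterol synthesis genes were lower with leucine than with alanine in 22 of 25 (median -0.24, 3 when adjusted over the list alone, adjusted p = 0.422 with an estimated correlation). Oxidative phosphorylation genes were higher in 48 of 52 (median 0.36, 0 when adjusted over the list alone, adjusted p = 0.554 with an estimated correlation), and leucine LPLFD library 3, with its score of 1.18 for oxidative phosphorylation, is in this comparison. Distal colon markers were higher with leucine in 6 of 7 (median 0.44, adjusted p = 0.00156 at the preset correlation and 0.422 with an estimated correlation), and alanine LPLFD library 5 had the distal score of -4.40. The 95% interval of the difference lay within 2-fold for 85.9% of 13594 genes. The count of 2 became 0 without any of alanine libraries 1 to 5 or leucine libraries 3 or 4, 5 without leucine library 1 and 1 without leucine library 5, and it was 12 without the 5 libraries that stood apart. It was 0 in a fit of only the groups compared, with no low-count filter, with the distal position score as a term and with the replicate block, and DESeq2 called 63 and limma voom 31. On this diet the Pearson r of the leucine and alanine effects was 0.541 across 19866 genes (not independent replicates). From differences of mean log2 CPM r was 0.552 and the covariance 0.120, against means of 0.489 and 0.0748 in simulations with shared vehicle (r from 0.123 to 0.739), and r was 0.216 with the vehicle libraries split.

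In mice given leucine, LPLFD lowered genes of tuft and goblet cells relative to the control diet. Dclk1, a marker of tuft cells, fell from 21.5 ± 3.59 to 8.37 ± 2.71 CPM (SD, n = 5 per group, log2 fold change -1.36 ± 0.26, adjusted p = 0.0153, edgeR). Trpm5, their taste transduction channel, fell from 13.2 ± 4.05 to 5.21 ± 1.35 CPM (-1.34 ± 0.29, adjusted p = 0.0334, edgeR). Of 16 tuft cell genes 16 were lower (median -1.14), 4 over all genes and 11 when adjusted over the list alone. Of 26 goblet cell and mucus genes 22 were lower (median -0.57), 6 over all genes and 11 when adjusted over the list alone, among them Fer1l6 (-0.80 ± 0.12) and Clca1 (-0.98 ± 0.16). Both lists were called at the preset correlation (adjusted p = 3.33e-16 and 1.85e-13) and with an estimated correlation (adjusted p = 0.0279 for each). With that correlation neither list passed without leucine LPLFD library 1, 2, 4 or 5 (adjusted p = 0.0866, 0.0982, 0.0842 and, for goblet and tuft genes, 0.0622 and 0.0711) or without leucine control library 4 (adjusted p = 0.0606). The tuft cell score was -0.40 ± 0.23 on LPLFD and 0.77 ± 0.32 on the control diet, and the goblet cell score -0.25 ± 0.15 and 0.30 ± 0.32 (n = 5 per group, exact two-sided permutation p = 0.00794 for each, 0.146 adjusted over the lists). Duox2 (-0.97 ± 0.18) and Nox1 (-1.16 ± 0.23) fell, and Aqp8, a water channel of the colon surface, rose from 496 ± 75.8 to 942 ± 265 CPM (0.93 ± 0.22), as did the metallothionein gene Mt1 (1.53 ± 0.32) and Ftl1 (0.88 ± 0.18). Cholesterol synthesis genes were lower in 21 of 25 (median -0.33), 0 over all genes and 10 down and 2 up when adjusted over the list alone (adjusted p = 0.422 with an estimated correlation). Smooth muscle markers were lower in 11 of 11 (median -2.19, adjusted p = 0.441 with an estimated correlation).

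Under leucine the diet raised 31 genes and lowered 61 (edgeR, 2712 at an unadjusted p under 0.05), and 2 of 19 lists called at the preset correlation held with the estimated one. The count of 92 became 36 without leucine LPLFD library 4 and 21, 45, 15 and 21 without leucine control libraries 1 to 4. A fit of only the groups compared called 0 genes, so the named tuft and goblet genes did not pass in it, the replicate block left 50 and no low-count filter gave 60. It was 335 without the 5 libraries that stood apart, and DESeq2 called 393 and limma voom 451.

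**Figure D4:**
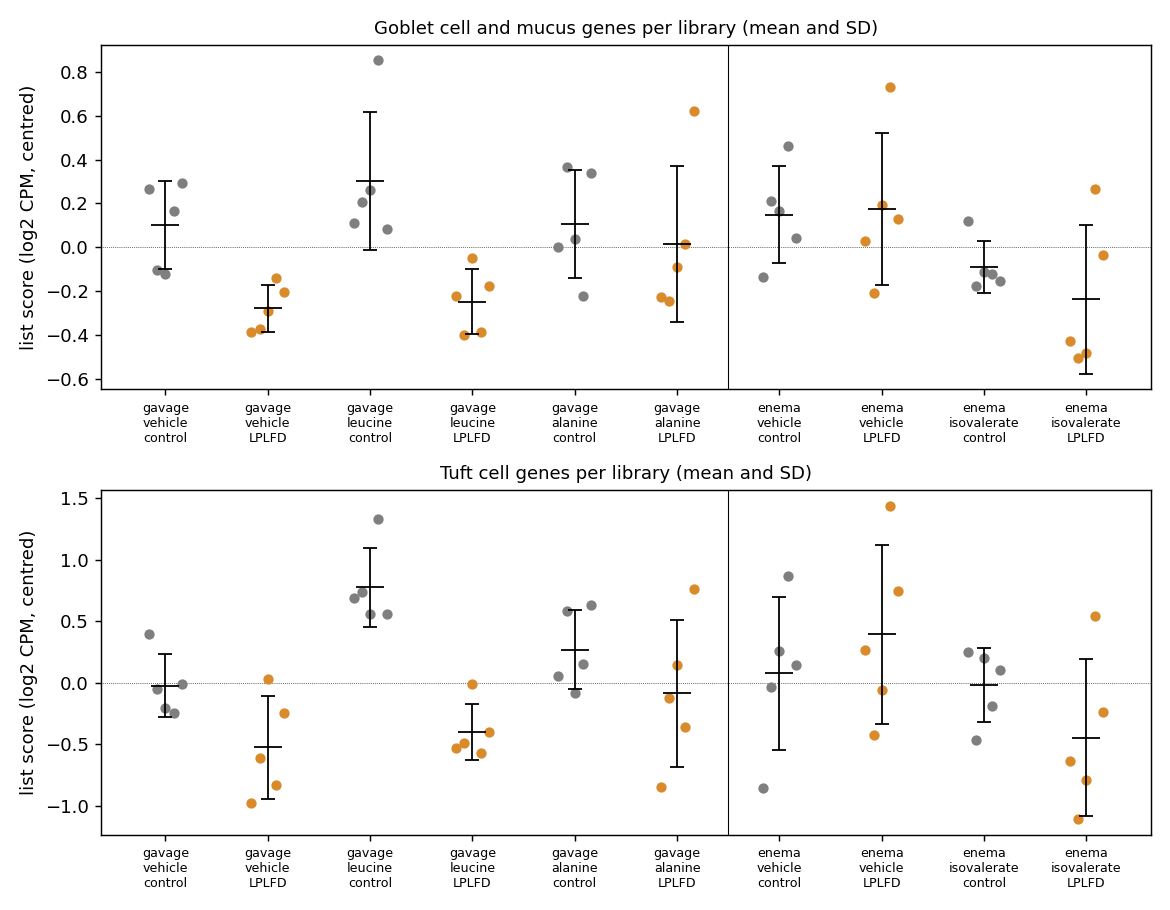
Scores of the goblet cell and mucus list and of the tuft cell list in each library of the 10 groups, as mean log2 CPM centred within each experiment. Lines show the group mean and SD (n = 5 per group).

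In mice given alanine, LPLFD lowered 4 genes and raised 0 (edgeR, 985 at an unadjusted p under 0.05). Other fits gave genes in both directions: DESeq2 called 3 up and 9 down, with 4 of the 4 among them, and limma voom 4 up and 6 down, with 2 of the 4. Without the 5 libraries that stood apart 2 genes rose and 1 fell, and 0 of the 4 were among them. Slc39a4, a zinc transporter, fell from 82.3 ± 10.5 to 43.9 ± 7.84 CPM (SD, n = 5 per group, log2 fold change -0.91 ± 0.16, adjusted p = 0.0348, edgeR). Bnip5 (-0.92 ± 0.16), Ifit1bl1 (-1.18 ± 0.22) and Spats2l (-1.13 ± 0.21) fell, each lower in 5 of 5 libraries. Genes of electrolyte and water transport were lower in 21 of 28 (median -0.16), 0 over all genes and 1 when adjusted over the list alone, Hsd11b2, the enzyme that shields the mineralocorticoid receptor from glucocorticoids. The list was called at the preset correlation (adjusted p = 7.34e-07) and with an estimated correlation (adjusted p = 0.0136). Without alanine control library 1 the estimated correlation gave adjusted p = 0.0536. The score of electrolyte and water transport was -0.95 in alanine LPLFD library 5 against -0.13 to -0.00127 in the other libraries of that group. Cell cycle genes were lower in 33 of 35 (median -0.28, 0 when adjusted over the list alone, adjusted p = 0.726 with an estimated correlation). The count of 4 became 0 without LPLFD libraries 1, 3 or 4 or control library 1, 1 without LPLFD library 5 or control library 2, and 2 without control library 3. A fit of only the groups compared called 0, the replicate block 1 and the distal position term 2.

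Interaction contrasts asked whether an amino acid acted differently on the 2 diets. For alanine, 2 genes had a lower effect on LPLFD than on the control diet, Irf2bpl (log2 difference -0.93 ± 0.17) and Phf13 (-0.88 ± 0.16, both adjusted p = 0.0409, edgeR). Both were lowest with water on the control diet: Irf2bpl was at 28.6 CPM there, against 43.7 with water on LPLFD and 55.3 and 44.2 with alanine on the control diet and on LPLFD, and Phf13 at 13.5 against 22.6, 23.9 and 21.9 CPM. They also rose with leucine on the control diet. Of 25 cholesterol synthesis genes 23 had a higher effect of alanine on LPLFD (median difference 0.85), 0 over all genes and 19 when adjusted over the list alone, and the list was called at the preset correlation (adjusted p = 1.99e-22) and with an estimated correlation (adjusted p = 0.0149). Of 31 junction genes 26 had a lower effect on LPLFD (median -0.16, 0 over all genes or when adjusted over the list alone, adjusted p = 0.00199 at the preset correlation and adjusted p = 0.0149 with an estimated correlation). Without alanine control library 1 the junction list had adjusted p = 0.0564 with that correlation. Markers of other cells differed too: the effect on LPLFD was higher for T and intraepithelial lymphocytes in 16 of 17 (median 0.93, adjusted p = 9.06e-06 at the preset correlation) and for fibroblasts in 13 of 14 (median 1.21, adjusted p = 0.00747), with adjusted p = 0.293 and 0.590 with an estimated correlation. With edgeR 1056 genes had an unadjusted p under 0.05 for alanine by diet, and DESeq2 called 5 and limma voom 23. For leucine by diet 0 genes passed (edgeR, 925 at an unadjusted p under 0.05, DESeq2 0, limma voom 0). Of 52 oxidative phosphorylation genes 51 had a higher effect of leucine on LPLFD and of 16 tuft cell genes 15 a lower one (medians 0.46 and -0.61, 0 of either when adjusted over the list alone), with adjusted p = 0.845 with an estimated correlation for both. Leucine LPLFD library 3 had an oxidative phosphorylation score of 1.18 (-0.06 to 0.15 in the others of its group), and leucine control library 4 a tuft cell score of 1.33 (0.56 to 0.74). The 2 genes for alanine by diet became 1 without alanine LPLFD library 4, and 6 without vehicle control library 5. It stayed at 2 without vehicle LPLFD library 4 or vehicle control library 1, and was 0 without any other library of these groups. Without the 5 libraries that stood apart it was 15, and it was 0 with GC and length offsets, in 1 fit of all 50 libraries, with no low-count filter, with the distal position score as a term and with the replicate block.

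Isovalerate on LPLFD asked what the fatty acid named in the series title did to the malnourished colon, and no gene passed. With edgeR 0 of 18614 genes passed, 1250 had an unadjusted p under 0.05, DESeq2 called 21 and limma voom 0. Goblet cell and mucus genes were lower with isovalerate in 24 of 26 (median -0.45, 6 when adjusted over the list alone). Among them Fer1l6 was at 51.8 ± 14.3 CPM with isovalerate and 88.2 ± 7.61 with saline (SD, n = 5 per group, log2 fold change -0.77 ± 0.16, lower in 5 of 5 libraries, adjusted p = 0.310, edgeR). Muc2, the main gel-forming mucin, had -1.16 ± 0.40 (adjusted p = 0.658, edgeR). Tuft cell genes were lower in 16 of 16 (median -0.89, 3 when adjusted over the list alone), and crypt base and stem cell genes in 19 of 21 (median -0.25, 0 when adjusted over the list alone). Over the 42 goblet and tuft markers the median was -0.61, and -0.29 without vehicle LPLFD library 4 and -0.25 with the distal position score as a term. The goblet, tuft and stem cell lists were called at the preset correlation and had adjusted p = 0.169, 0.306 and 0.246 with an estimated correlation. Endothelial markers were lower in 7 of 7 (median -0.41, adjusted p = 0.00465 at the preset correlation) and anal squamous markers higher in 10 of 10 (median 0.25, adjusted p = 0.0248), with adjusted p = 0.215 and 0.619 with an estimated correlation. Genes of tight and adherens junctions were not called (18 of 30 higher, median 0.04, adjusted p = 0.540 at the preset correlation), nor were those of short-chain fatty acid sensing (8 of 14 higher, adjusted p = 0.972 at the preset correlation). The vehicle group holds library 4 with the low distal score of -4.34 for colon position distal, and without vehicle LPLFD library 2 or library 4, or without the 5 libraries that stood apart, the count was 1.

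Isovalerate on the control diet also gave 0 genes of 18614 (edgeR, 1058 at an unadjusted p under 0.05, DESeq2 9, limma voom 0). Tppp, a tubulin-binding protein gene, was at 62.9 ± 3.98 CPM with isovalerate and 111.3 ± 20.82 with saline (SD, n = 5 per group, log2 fold change -0.82 ± 0.17, lower in 5 of 5 libraries, adjusted p = 0.358, edgeR). Erythroid markers, which come from blood in the sample, were lower in 5 of 5 (median -1.07, 0 over all genes and 2 when adjusted over the list alone), called at the preset correlation (adjusted p = 2.63e-05) and with an estimated correlation (adjusted p = 0.0486). With the latter it did not pass in 7 of 10 leave-outs of a library, with adjusted p up to 0.197. Interferon response genes were higher in 40 of 40 (median 1.77, 0 over all genes and 23 when adjusted over the list alone), with adjusted p = 0.529 with an estimated correlation. The score for interferon response was 3.70 in isovalerate control library 1 against -0.65 to 0.37 in the other libraries of its group. Antigen presentation genes of class II were higher in 7 of 9 (median 2.88, 5 when adjusted over the list alone, adjusted p = 0.617 with an estimated correlation), with a score for antigen presentation class II of 4.33 in that library against -0.64 to 0.23. Without vehicle control library 3 the count was 1.

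Under isovalerate the diets did not differ by any gene past the threshold (edgeR 0 of 18614, 907 at an unadjusted p under 0.05, DESeq2 1, limma voom 0). Interferon response genes were lower on LPLFD in 40 of 40 (median -1.71, 24 when adjusted over the list alone, adjusted p = 0.573 with an estimated correlation), with isovalerate control library 1 in the control group. The isovalerate by diet interaction had 0 genes (edgeR, 636 at an unadjusted p under 0.05, DESeq2 0, limma voom 0). Cholesterol synthesis genes had a higher effect of isovalerate on LPLFD than on the control diet in 25 of 25 (median difference 0.39, 1 when adjusted over the list alone, adjusted p = 0.626 with an estimated correlation).

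Leucine by gavage and isovalerate by enema on LPLFD are set side by side, though route, dose, vehicle and duration differ. Ribosomal protein genes had medians of 0.61 with leucine and 0.05 with isovalerate, tuft cell genes 0.13 and -0.89, goblet cell genes 0.08 and -0.45 and oxidative phosphorylation genes 0.56 and 0.09, and the differences between these were not tested. Single libraries moved these medians: over the 110 ribosomal and oxidative phosphorylation genes that with leucine went from 0.58 to 0.17 without leucine LPLFD library 3, and over the 42 goblet and tuft markers that with isovalerate from -0.61 to -0.29 without enema vehicle LPLFD library 4. Across 18425 genes the effects had a Pearson r of -0.0830 and a Spearman rho of -0.0511, where genes are not independent replicates. Of 58 genes that passed with leucine on LPLFD, 27 had the same sign with isovalerate.

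Whether a treatment on LPLFD ran against the diet effect was compared across genes, which are not independent replicates. Pearson r between the diet effect under vehicle and the treatment effect on LPLFD was -0.368 for leucine, -0.454 for alanine and -0.564 for isovalerate. Both effects share the vehicle LPLFD libraries. From differences of mean log2 CPM r was -0.314, -0.464 and -0.495, and simulations of unchanged groups that share them gave means of -0.494, -0.516 and -0.492 by that estimate. With the vehicle libraries split so that none was shared, r was -0.0294, -0.108 and 0.0188. The covariance by the same estimate was -0.0670, -0.0857 and -0.0766, against -0.0779, -0.0835 and -0.0698 in the simulations. Of the 38 genes that fell on LPLFD under water gavage, the median effect was 0.07 with leucine and 0.32 with alanine, and of the 48 that rose it was 0.10 and -0.11.

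Markers of other cells were called at the preset correlation in further comparisons, with adjusted p from 0.258 to 0.845 with an estimated correlation. Fibroblast markers were higher with leucine on the control diet in 13 of 14 (median 0.46) and against alanine there in 13 of 14 (1.23), with alanine on LPLFD in 12 of 14 (0.59), and on LPLFD under alanine in 12 of 14 (0.97) and under isovalerate in 13 of 14 (1.05). They were lower on LPLFD under leucine in 13 of 14 (-0.69) and with isovalerate on the control diet in 12 of 14 (-0.84). Myeloid markers were higher on LPLFD under alanine in 12 of 16 (0.31) and under enema vehicle in 11 of 17 (0.14), and with isovalerate on the control diet in 14 of 17 (0.42). Erythroid markers were higher on LPLFD with leucine and with alanine in 5 of 5 each (1.90 and 1.38), and anal squamous markers with leucine on the control diet in 7 of 9 (0.58). For the interactions with diet, the marker lists called were, for leucine, T and intraepithelial lymphocytes (higher on LPLFD in 13 of 17, 0.46) and smooth muscle (lower in 11 of 11, -1.43), and, for isovalerate, anal squamous (higher in 9 of 10, 0.42) and myeloid markers (lower in 12 of 17, -0.62). The diet effect was higher under enema than under gavage for T and intraepithelial lymphocytes in 16 of 19 (0.74) and fibroblasts in 12 of 14 (1.17).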

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

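The tests on the 3 patterns weighed first and the other splits of the libraries for diet under water gavage, and the comparison of splits by unadjusted counts, were chosen after the result was seen.

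Of the genes called for diet under water gavage, leucine on the control diet and alanine on the control diet, 34 passed in 2 or more and 13 in all 3. These comparisons share the 5 control water libraries, so an overlap is expected from sharing alone, and its size without a change was not computed. In comparisons without those libraries the sign of the diet effect was there for 32 of the 34 with leucine on LPLFD, 26 with alanine on LPLFD, 29 for diet under leucine and 15 for diet under alanine (median signed log2 fold changes 0.31, 0.07, 0.16 and -0.02), though each of these shares another group with 1 of the 3. With GC and length offsets 88.9% of their 81 calls stayed, which argues against such a trend as the whole cause. Leaving out 1 control water library kept 93.03% or more of the median diet effect. Those libraries chose the genes, so a single library stays open as cause. Whether the diet has this effect in general stays open, since under saline enema the median signed diet effect of these genes was 16.1% of that under gavage, with 24 of 33 in the same direction but a spread wider than the difference. Library numbers run group by group in the gavage experiment, so an order of preparation cannot be told apart from the groups.

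Cytosolic ribosomal protein and oxidative phosphorylation genes were higher with leucine on LPLFD, with a median log2 fold change of 0.58 over 110 members. Without leucine LPLFD library 3 the median was 0.17, so that 1 library may hold most of the rise. With GC and length offsets it was 0.31, so a length trend stays open as a part of it (SD of the change over the members 0.20). A biological effect of leucine on these genes was not shown apart from that library.

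Goblet and tuft cell markers were lower on LPLFD with leucine (median log2 fold change -0.78 over 42 markers, against leucine on the control diet) and with isovalerate (-0.61, against vehicle on LPLFD). In the leucine comparison the median was -0.65 with the distal position score as a term, which argues against colon position as the whole cause. Without the most influential library 81.2% of it stayed, but single markers moved by more (SD 0.69), so the part of that library stays open. In the isovalerate comparison the median was -0.25 with the position term, and 47.8% of it stayed without enema vehicle LPLFD library 4, which also had the lowest distal score of its group, so colon position or that 1 library may account for most of the decrease.

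Other splits of the libraries into groups of the same sizes (litter unknown) were fitted with edgeR, 100 per comparison, the real split among them. By the count of called genes chance could be excluded for diet under water gavage (86 genes, highest other split 2), leucine on the control diet (64, highest other 2), leucine on LPLFD (58, highest other 1), alanine on the control diet (38, highest other 6), diet under leucine (92, highest other 23), diet under alanine (4, highest other 1) and the diet effect by experiment (5, highest other 4), each reached by 1 of the 100 splits, the real one. For leucine against alanine on LPLFD 3 of the 100 splits gave as many as the 2 called genes. That share is small, but the highest other split called 65, so chance is not excluded. The 65 point to a structure of the samples other than the groups. For the alanine by diet interaction 2 of the 100 splits gave as many as the 2 called genes. Another split called 6, so chance is not excluded. By the number of genes at an unadjusted p under 0.05 the real split of the groups was reached by 18 of the 100 splits for diet under leucine (2712, highest other 4031), 20 for diet under alanine (985, highest other 1588), 42 for leucine against alanine on LPLFD (2235, highest other 4431), 4 for the alanine by diet interaction (1056, highest other 1521) and 2 for leucine on LPLFD (3487, highest other 3492), and for the others of these comparisons by 1, the real one. So for diet under leucine or alanine the calls argue against chance but the unadjusted counts do not. For leucine against alanine on LPLFD neither count excludes chance. Where 0 genes were called, all 100 splits reach that count by construction, which says nothing about chance, and only the unadjusted counts can be compared. For alanine on LPLFD (highest other 1 by calls, DESeq2 11, limma voom 0) only the real split reached the 1542 unadjusted genes (highest other 1448, median 790). This argues against chance for that count with all libraries but does not exclude it. That count was 691 without alanine LPLFD library 5, which had the lowest distal score, 625 with the position term and 1534 without the 5 libraries that stand apart. The unadjusted count did not argue against chance for leucine against alanine on the control diet (highest other 1 by calls, 635 unadjusted, reached by 19, DESeq2 1, limma voom 0) or the leucine by diet interaction (8, 925, reached by 44, DESeq2 0, limma voom 0). Nor did it in the enema experiment for diet under vehicle (highest other 10 by calls, 1626 unadjusted, reached by 14, DESeq2 24, limma voom 1), isovalerate on the control diet (4, 1058, reached by 21, DESeq2 9, limma voom 0) and on LPLFD (1, 1250, reached by 28, DESeq2 21, limma voom 0). The same was so for diet under isovalerate (0, 907, reached by 17, DESeq2 1, limma voom 0) and the isovalerate by diet interaction (17, 636, reached by 70, DESeq2 0, limma voom 0). The 10 genes of another split of the diet groups under enema vehicle point to a structure of those samples too. For the 3 interactions of a treatment with diet the highest other split (6, 8 and 17) depends on which splits were drawn, so no structure is read from it. Splits were not refitted without single libraries, and leaving out 1 library took the calls to 0 for leucine on LPLFD (without vehicle LPLFD library 3), for diet under alanine (without LPLFD libraries 1, 3 or 4 or control library 1), for leucine against alanine on LPLFD (without any of alanine libraries 1 to 5 or leucine libraries 3 or 4), for the alanine by diet interaction (without any library of its groups but alanine LPLFD 4, vehicle LPLFD 4 and vehicle control 1 and 5) and for the diet effect by experiment (without enema vehicle LPLFD libraries 3, 4 or 5, enema vehicle control library 5, gavage vehicle LPLFD libraries 2 or 4, or gavage vehicle control libraries 1, 3 or 4). It took the unadjusted genes to 2189 for leucine on LPLFD (without leucine library 3) and from 2023 to 1326 for leucine on the control diet (without leucine library 4).

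Of 178 groups tested for a library far from the other 4, 25 were flagged, where chance flags about 1 in 20 groups, or 8.9. Isovalerate control library 1 had an interferon score of 3.70 (others -0.65 to 0.37), a class II antigen presentation score of 4.33 (-0.64 to 0.23) and a goblet score of 0.12 (-0.18 to -0.11). Enema vehicle control library 4 had scores of 0.95 for interferon (-0.67 to -0.27) and 1.74 for class II antigen presentation (-0.94 to -0.49), and library 2 of that group -0.19 for cholesterol synthesis (0.21 to 0.32). Enema vehicle LPLFD library 4 had a distal score of -4.34 (-0.48 to 0.79), and library 2 had Fer1l6 at 75 CPM (88.4 to 93.2). Leucine LPLFD library 3 had scores of 1.44 for cytosolic ribosomal proteins (-0.15 to 0.10) and 1.18 for oxidative phosphorylation (-0.06 to 0.15), with Rps29 at 435 CPM (162 to 188), Ndufb1 at 85.7 (25.6 to 36.3) and Aqp8 at 1401 (748 to 935). Leucine LPLFD library 4 had a cell cycle score of -0.93 (-0.37 to -0.16). Leucine control library 4 had scores of 0.85 for goblet cells (0.08 to 0.26), 1.33 for tuft cells (0.56 to 0.74) and 0.17 for junctions (0.06 to 0.08), with Dclk1 at 27.9 CPM (19.1 to 20.7). Alanine control library 1 had 12.2% mitochondrial counts (6.06% to 7.64%), a TMM factor of 0.925 (1.00 to 1.03) and a ribosomal protein score of -0.40 (-0.04 to 0.11). In alanine control library 5 the cholesterol synthesis score was 0.22 (-0.05 to 0.02) and in library 4 the interferon score was -0.58 (0.11 to 0.22). Alanine LPLFD library 4 had a TMM factor of 1.04 (0.990 to 1.00), and library 5 a distal score of -4.40 (0.13 to 0.50).

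Effects that differed between groups were tested as interactions. The alanine effect was lower on LPLFD than on the control diet for Irf2bpl (log2 difference -0.93) and Phf13 (-0.88), and over the junction list (median -0.16), and higher over the cholesterol synthesis list (median 0.85). The diet effect under enema was higher than under gavage for Btn1a1 (3.82), and lower for Epha2 (-3.13) and Atosb (-0.99). For Gm74518 the difference was -8.34, a fitted value that bounds nothing, because the gavage vehicle libraries on the control diet had no counts of it (0.226 CPM on LPLFD, and under enema 0.167 CPM on the control diet and 0.0321 on LPLFD).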

How the results depend on the processing

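The GC and length offsets, the position term, the halved counts, the fits without the 5 libraries that stand apart and the leave-outs of the gene lists were tests chosen after the data had been seen, as was the replicate term for the agreement between comparisons. The other alternatives were fixed beforehand. Counts are of genes past an adjusted p of 0.05, and a count is given where it moved by more than 1.5 times from that of the edgeR fit in the report. It moved so under 30 of 32 settings for the diet effect by experiment, 27 of 32 for the alanine by diet interaction, 19 of 22 for leucine against alanine on LPLFD and 18 of 22 for leucine on LPLFD. Some of the genes called for leucine or alanine on the control diet and for diet under water gavage stayed called under every alternative run. Each named gene kept its direction under every alternative that gave it a value. The simulations recovered 44.4% (gavage) and 56.0% (enema) of 2-fold changes. The cause was not tested unless a sentence gives it.

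DESeq2 called 792 genes for leucine on LPLFD, 181 for leucine on the control diet, 11 for alanine on LPLFD, 1.0e2 for alanine on the control diet (78 up and 24 down), 63 for leucine against alanine on LPLFD and 1 on the control diet. For diet it called 306 under water gavage, 393 under leucine, 12 under alanine, 24 under enema vehicle and 1 under isovalerate, with 21 for isovalerate on LPLFD, 9 on the control diet, 5 for the alanine by diet interaction and 43 for the diet effect by experiment. Limma voom with quality weights called 955 for diet under water gavage, 451 under leucine, 10 under alanine, 1 under enema vehicle and 36 by experiment, with 408 for leucine on LPLFD, 492 on the control diet, 354 for alanine on the control diet, 31 for leucine against alanine on LPLFD and 23 for the alanine by diet interaction. The cause was not tested.

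With all 50 libraries in 1 fit, leucine on LPLFD had 846 called genes, leucine against alanine on LPLFD 11, isovalerate on LPLFD 1 and the alanine by diet interaction 0. Diet had 144 under water gavage, 145 under leucine, 2 under alanine and 7 under isovalerate. A fit of only the groups compared called 0 genes for leucine on LPLFD, leucine against alanine there and diet under leucine or alanine. The same fit called 1140 for diet under water gavage, 235 and 154 for alanine and leucine on the control diet, 1 for alanine on LPLFD and 5 for the alanine by diet interaction. Without a low-count filter the calls numbered 54 for diet under water gavage, 60 under leucine, 2 under enema vehicle and 2 by experiment. For leucine they numbered 2 on LPLFD and 40 on the control diet, for alanine on the control diet 25, for isovalerate on the control diet 4, and 0 for both leucine against alanine on LPLFD and the alanine by diet interaction. With at least 5 CPM in 5 libraries they numbered 208 for leucine on LPLFD, 6 against alanine, 150 for diet under water gavage, 147 under leucine and 12 by experiment. The last 2 filters test more or fewer genes by construction. RLE factors called 10 by experiment. A term for the run of library numbers in the enema experiment left 0 by experiment and gave 1 for isovalerate on LPLFD. The cause was not tested.

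With GC and length offsets the calls numbered 451 for leucine on LPLFD, 89 up and 12 down (1.0e2) on the control diet, 20 against alanine on LPLFD, 142 for diet under water gavage, 172 under leucine, 14 by experiment, 0 for the alanine by diet interaction and 1 for the leucine by diet interaction. Halved counts gave 132 for leucine on LPLFD and 9 by experiment. With the distal position score as a term the calls numbered 185 for leucine on LPLFD, 206 on the control diet, 0 against alanine on LPLFD, 2 for diet under alanine, 1 under enema vehicle, 0 by experiment, 1 for isovalerate on LPLFD, 1 on the control diet and 0 for the alanine by diet interaction. Without the 5 libraries that stand apart they numbered 1041 for diet under water gavage, 335 under leucine, 2 under enema vehicle and 48 by experiment. Leucine then had 259 on LPLFD, 259 on the control diet and 12 against alanine on LPLFD, alanine had 326 on the control diet, isovalerate had 1 on LPLFD and the alanine by diet interaction had 15. For diet under alanine 2 genes then rose and 1 fell, with 0 of the 4 genes of the report among them.

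Replicate numbers pair no samples by the labels. Over the 75 pairs of gavage libraries that share a number the median residual correlation was 0.00524, with 1 above 0.1, and in 11 of these pairs the first library correlated best with its own number in the other group. Over the 30 enema pairs it was 0.00323, with 4 above 0.1, and the own number was best in 9. With the replicate number as a block, 1 gene was called for leucine on LPLFD, 38 on the control diet, 0 against alanine on LPLFD, 50 for diet under leucine, 1 under alanine, 0 by experiment and 0 for the alanine by diet interaction. The block gave 66 for diet under water gavage and 27 for alanine on the control diet. The cause was not tested.

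Of the 235 list calls at the preset correlation, 8 passed with an estimated correlation and 16 with fry. With RLE factors 234 passed in the same direction, with the replicate block 228, with the position term 183 and without the 5 libraries that stand apart 170. With the filter of 5 CPM 204 of the lists could be tested and 177 passed, and in a fit of only the groups compared 218 of 231. With the position term 6 list calls changed direction, 4 of them of the distal markers from which the term is made: distal markers by experiment (adjusted p = 0.896), under water gavage (0.730), under leucine (0.844) and with isovalerate on LPLFD (0.859), and the cell cycle list for alanine on LPLFD (0.626) and for the alanine by diet interaction (0.786). Without the 5 libraries 3 changed direction: class II antigen presentation with isovalerate on the control diet (adjusted p = 0.512), cell cycle for the isovalerate by diet interaction (0.923) and fatty acid oxidation for diet under alanine (0.578). The cause of the other reversals was not tested.

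For the leucine and alanine effects the correlation, from differences of mean log2 CPM, was 0.216 on LPLFD and 0.214 on the control diet when each effect was computed against its own part of the vehicle libraries. In the same split the correlation of the diet effect with the treatment effect became -0.108 for alanine and -0.0294 for leucine, and for isovalerate it turned to 0.0188. The split removes the shared vehicle libraries by construction and leaves 2 or 3 of them to each effect. Over genes of at least 5 CPM the correlation for leucine was -0.141, and the cause was not tested.

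Leaving out 1 library at a time gave ranges of called genes of 23 to 91 for diet under water gavage, 15 to 118 under leucine, 0 to 4 under alanine, 0 to 2 under enema vehicle, 0 to 0 under isovalerate and 0 to 20 by experiment. For leucine they were 0 to 830 on LPLFD, 15 to 56 on the control diet, 0 to 5 against alanine on LPLFD and 0 to 0 on the control diet. For alanine they were 0 to 0 on LPLFD and 10 to 38 on the control diet, and for isovalerate 0 to 1 on LPLFD and 0 to 1 on the control diet. The interactions ran from 0 to 6 for alanine, 0 to 0 for leucine and 0 to 0 for isovalerate. The list calls ran from 219 to 242. Correlations ran from -0.120 to 0.0187 for diet between the experiments, -0.102 to 0.0227 for isovalerate with leucine on LPLFD, 0.479 to 0.593 for leucine with alanine on LPLFD and 0.524 to 0.663 on the control diet. For the diet effect against each treatment they ran from -0.535 to -0.381 for alanine, -0.645 to -0.427 for isovalerate and -0.447 to -0.320 for leucine.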

Other observations

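The 2 permutation tests of the cholesterol synthesis score were chosen after the result was seen.

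In the enema experiment the list of clock genes was called at the preset correlation in 4 comparisons and in none of them with an estimated correlation. Of 16 measured members of the circadian list 14 were lower on LPLFD than on the control diet under vehicle (median log2 fold change -0.20, adjusted p = 0.000278 at the preset correlation, adjusted p = 0.392 with an estimated correlation). With isovalerate 12 of 16 were lower on the control diet (-0.24, adjusted p = 0.000970, and adjusted p = 0.317 with an estimated correlation) and 13 of 16 on LPLFD (-0.14, adjusted p = 0.0277, and adjusted p = 0.428 with an estimated correlation). Under isovalerate 13 of 16 were lower on LPLFD than on the control diet (-0.30, adjusted p = 0.00155, and adjusted p = 0.544 with an estimated correlation). No member passed over all genes in these comparisons. For Per2 the log2 fold changes were -0.57 ± 0.22, -0.70 ± 0.22 and -0.45 ± 0.22 for diet under vehicle and for isovalerate on the control diet and on LPLFD (SE, n = 5 per group). The score of the list was 0.24 ± 0.11 with vehicle on the control diet, -0.05 ± 0.08 with vehicle on LPLFD, 0.03 ± 0.10 with isovalerate on the control diet and -0.23 ± 0.21 with isovalerate on LPLFD (SD, n = 5 per group). Exact two-sided permutation p was 0.00794 for diet under vehicle, 0.0238 for isovalerate on the control diet, 0.135 on LPLFD and 0.0317 for diet under isovalerate, and after adjustment over the lists 0.182, 0.548, 0.534 and 0.580. The labels give no hour of sampling.

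Cholesterol synthesis genes were lower on LPLFD under vehicle in both experiments, and the hypothesis was that the diet lowers them wherever no treatment is added. The score differed between the diets by -0.69 under water gavage (exact two-sided permutation p = 0.00794) and by -0.28 under saline enema (exact p = 0.135), and with labels permuted within each experiment the exact two-sided permutation p of both together was 0.000756, so most of the evidence came from the gavage. Under treatment the differences were -0.35 with leucine (exact p = 0.0476), 0.01 with alanine (exact p = 0.976) and 0.16 with isovalerate (exact p = 0.151), a mean of -0.06 against -0.49 under vehicle. Permuted within each treatment, the mean had a two-sided permutation p of 0.465, which does not show that the diets were alike there, and the spread between the treatments (SD 0.26) keeps open whether the diet effect is also there under treatment. The hypothesis may hold for water gavage, stays open for the enema, and was found and tested on the same libraries.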
